A study of Mus musculus with 2 samples.

How the data were processed

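H3K9ac ChIP-seq was measured in stomach tissue pooled from mouse embryos of both sexes at embryonic day 14.5. There was 1 group of 2 biological replicates, which per the labels are separate biosamples that carry the same donor entry. The donor entry was read as the mouse strain, since the tissue was pooled from embryos of both sexes, but the labels do not say so. Replicate 1 had 1 technical replicate and replicate 2 merged 2, per the labels and the deposited read-me texts. As the groups come from labels alone and nothing tells how many embryos each pool held, differences between replicates mix biological and technical spread.

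The authors deposited peak lists in the narrowPeak layout on build mm10 (GRCm38). Per the deposited read-me texts, peaks were called on each replicate alone and on the pool of both, each against control alignments, and a replicated list was derived from the 3 others. The aligner, the peak caller, its settings, the replication rule and the read depth were not given in the sources used here. Each peak carries an enrichment signal value over its control that the authors deposited and that is not scaled between lists. It was therefore used to describe and rank peaks within a list, to compare X-linked with autosomal promoter peaks of the same list, and to correlate overlapping peaks of the replicates by rank and by log2 value. The deposited lists also give −log10 p and −log10 q per peak, and the lowest −log10 p was just above 2 in every list, so weak peaks are included. A −log10 q of at least 2 was reached by 58.3% of peaks in each replicate, 68.2% in the pooled list and 98.8% in the replicated list. The minimum width held 18.7% of peaks in replicate 1 and 27.0% in replicate 2. Control signal and reads were not analysed here, so neither the height of a promoter without a called peak nor a count of reads can be given, and the absence of a peak means only that none was called. Column 7 of the lists was used for enrichment, and 0 columns of the lists of the whole series were left unmatched.

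Peaks were read into Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and tests were run with scipy 1.17.1. Genes and transcripts were those of GENCODE release M21, and chromosome lengths and sequence came from the GRCm38 FASTA, indexed with samtools 1.23.1 and read with pysam 0.24.0. Figures were drawn with matplotlib 3.10.9. The background was all 21938 protein-coding genes on the 21 chromosomes with peaks, with 54361 starts of protein-coding transcripts. A gene had a promoter peak if a peak overlapped the 1000 bp either side of any of these starts, so both genes of a shared or bidirectional promoter are counted, and near-identical copies such as Hba-a1 and Hba-a2 can lose peaks where reads map to more than 1 place. Region classes were taken from the peak midpoint in the order promoter, exon, intron, intergenic. Random expectations came from 100 seeded placements of each peak on its own chromosome, which did not exclude assembly gaps or repeats. Peaks on scaffolds, 4 in the replicated list, were counted in the list totals and in the overlaps between lists. They were left out of the region classes, the random placements, the distal peaks and the counts per chromosome. Distal peaks lay more than 2500 bp from every annotated start of any transcript type. Regions were joined across gaps of up to 1000 bp.

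The 31 gene lists, with 585 entries and 567 distinct symbols, and the tests were fixed before the data were examined. Of the entries 584 were found in the annotation, the exception being Ahsp, and 16 genes stand in more than 1 list. Each list was tested against all other protein-coding genes with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over the 31 lists. The tests are across genes within these libraries, genes of 1 list are not independent, and no p-value measures a difference between embryos. As an alternative, 10000 random gene sets of the same size were drawn, matched in 10 bins on the CpG observed to expected ratio within 1000 bp of the 5′ end of the gene, and their two-sided p is called a permutation p. Genes were not matched on their number of transcript starts, although a peak at any start counted. For the 2 contrasts between classes of lists, genes in both classes (5 in the first) were left out of both. Overlap between lists was counted when it covered at least 50% of the shorter peak.

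Genes were named by a rule fixed before the data were examined: 12 genes always (Sox2, Barx1, Nkx3-2, Foxf1, Gata4, Hnf4a, Trp63, Acta2, Atp4b, Cdx2, Pdx1 and Alb), up to 4 members per list with the highest enrichment value and up to 3 without a peak in any list, taken in alphabetical order. To these came the genes of the 20 widest regions, the 10 highest peaks and 10 highest distal peaks with their nearest gene, and up to 8 list genes found in each replicate alone. Where these made a long list only part is printed, and genes outside the rule are said to have been chosen after their values were seen.

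The functions were tested on simulated data first. Of 5000 simulated peaks, 3000 were built to overlap by at least 50% and 3000 were found. For 300 simulated lists of 20 genes among 20000 with no enrichment, 3.67% passed an unadjusted threshold of 0.05 with Fisher's exact test. For 300 lists enriched only through CpG ratio, 71.3% passed that test and 4.00% the matched one, and of 300 lists with 18 of 20 genes marked, 100% passed both. The simulated chance of a peak depended on the matching bin alone, so effects of CpG ratio within a bin were not tested. All lists of the last kind held the same count by construction, so their result with Fisher's exact test was set in advance.

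Chosen before the data were examined, the other settings were a stricter threshold (−log10 q of at least 2), other overlap rules, joining peaks first, lists of equal length, promoter windows of 500 and 2500 bp, 1 start per gene, each replicate's list alone, the pooled list, CpG-matched sets, 1 gene per 100 kb, other joining distances (0 and 3000 bp) and other distances for distal peaks (1000 and 10000 bp). Pooled peaks overlapped in both replicates, and reciprocal overlap for the makeup of the replicated list, were added after the data were seen.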

Results

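Acetylation of histone H3 at lysine 9 (H3K9ac), a chromatin mark found at active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in stomach dissected from mouse embryos at embryonic day 14.5. At this stage the stomach is a tube of epithelium inside a layer of mesenchyme that is forming smooth muscle. The design held 1 group with 2 biological replicates, each a separate pool of stomachs from embryos of both sexes, so no comparison between groups was possible. The questions open to such a design are which promoters and regions carried H3K9ac in this organ, and how far the replicates gave the same regions. Replicate 1 held 36081 peaks covering 18 Mb, and replicate 2 held 64919 peaks covering 28.6 Mb. The pool of both replicates held 50041 peaks, and the authors' replicated list held 20341 peaks covering 21.3 Mb with a median width of 869 bp. Unless another list is named, the values below come from the replicated list, and the enrichment value of a peak is the authors' own. Read depth was not given in the sources used here, and confidence intervals (95%, Clopper-Pearson) cover counting error only.

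Most H3K9ac peaks of the replicated list lay at the starts of genes. Of 20337 replicated peaks on the assembled chromosomes, 73.6% (interval 73.0 to 74.3%) had their midpoint within 1000 bp of a protein-coding transcript start, against 2.64% for the same peaks placed at random, a 27.9-fold excess. Introns held 12.7% of the peaks against 41.1% at random, and intergenic sequence held 7.93% against 51.9%. Exons held 5.77% against 4.35%, but by the midpoint rule wide peaks that cover a start could fall in the exon or intron class. Among the 10 highest peaks this was so for exons at Tnrc18, Irf2bp2 and Rps19, and for introns at Bicral, Sfpq and Ptma. An excess in exons away from starts is therefore not shown. Of 3432 peaks more than 1000 bp from every annotated start, 13.4% lay in exons. Promoter peaks had a median enrichment value of 8.78 and a median width of 1009 bp, while intronic peaks had medians of 4.26 and 521 bp. The promoter share was 50.8% in the list of replicate 1 and 34.6% in that of replicate 2, where introns held more (36.2%), so a majority at promoters held for the replicated list and replicate 1 and not for replicate 2 or the pooled list (40.1%).

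**Figure D1:**
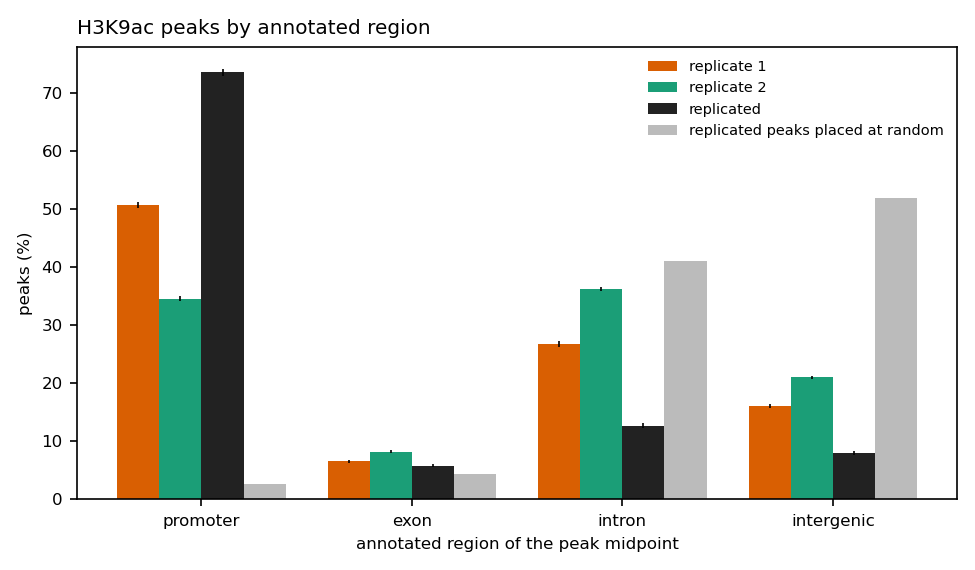
Share of H3K9ac peaks (y axis, %) by the annotated region of the peak midpoint (x axis) for replicate 1, replicate 2 and the replicated list, with 95% Clopper-Pearson intervals, beside the mean share of the replicated peaks placed at random 100 times. Promoters hold 73.6% of replicated peaks against 2.64% at random.

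A promoter peak was present at 12771 of 21938 protein-coding genes (58.2%, interval 57.6 to 58.9%). Replicate 1 had promoter peaks at 12569 genes and replicate 2 at 14057, of which 12370 were the same genes. A further 199 genes had a promoter peak in replicate 1 and not in replicate 2, 1687 the reverse, and 7469 genes had none in any list. The share followed promoter sequence: in the decile of genes with the lowest ratio of observed to expected CpG dinucleotides 2.42% had a peak, and in the decile with the highest ratio 96.9% did. Each gene list below was therefore tested both against all other protein-coding genes and against random genes matched on this ratio.

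Regulators of the stomach mesenchyme carried H3K9ac at nearly every promoter. Of 20 such genes 19 had a promoter peak, against 58.2% of other genes (Fisher's exact test, adjusted exact p = 9.45e-04), and the same number had one in replicate 1. Barx1, a homeobox gene needed for stomach specification, had an enrichment value of 13.9 in the replicated list, 9.28 in replicate 1 and 20.1 in replicate 2. Its peak at chromosome 13, 48662903 to 48667216, covered the start of the gene. Foxf1, a forkhead factor of gut mesenchyme, reached 17.8 (11.7 and 20.2 in the replicates), and Nkx3-2, a homeobox gene of stomach and spleen mesenchyme, reached 7.98 (5.88 and 7.41). The highest values of the list were those of the homeobox genes Meis1 (28.8) and Meis2 (22.1) and the nuclear receptors Nr2f2 (28.7) and Nr2f1 (22.8). The exception was Nkx2-3, named after its values were seen, which had a peak in replicate 2 (4.94) and in the pooled list (3.46) and none in the others. Random genes matched on CpG ratio had a peak in 87.9% of cases, and against these the list did not stand apart (adjusted permutation p = 0.634). At that share even 20 of 20 genes would have given an unadjusted permutation p of 0.0914, so the matched test could not have kept the call.

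Smooth muscle and fibroblast genes had promoter peaks more often than genes of like CpG ratio. Visceral smooth muscle genes had a peak at 18 of 20 promoters (adjusted exact p = 0.00486), where CpG-matched genes had one in 51.7% (adjusted permutation p = 6.89e-04, the smallest the random sets allow after adjustment). Srf, the transcription factor that drives contractile genes, had an enrichment value of 30.8, Tpm1 17.4, Smtn 11.2 and Tpm2 10.9, and Acta2, smooth muscle actin, had 6.38 (5.92 and 8.13 in the replicates). Pln had no peak in any list. In replicate 1 alone 15 of the 20 had a peak and the call was lost (adjusted exact p = 0.142), and it was also lost among pooled peaks overlapped in both replicates (adjusted exact p = 0.136). Fibroblast and extracellular matrix genes had a peak at 16 of 20 promoters, which did not pass against all other genes (adjusted exact p = 0.0868) but did against the 44.5% of CpG-matched genes (adjusted permutation p = 6.89e-04). Among them were the collagens Col5a1 (enrichment value 18) and Col1a1 (17.2), the receptor Pdgfra (15.2) and the matrix protein Sparc (15.2), while Dpt, Mfap5 and Postn had no peak in any list.

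Among lists of epithelial genes, those shared by many epithelia were marked more often than other genes, and products of the mature glands and of squamous and endocrine cells less often. The samples were stomach tissue, so no peak can be assigned to the epithelium. How far a low number of cells of a type lowers the share of its genes was not tested. General epithelial adhesion and keratin genes had a peak at 19 of 20 promoters (adjusted exact p = 9.45e-04, and 0.0145 against CpG-matched genes), with enrichment values of 14.1 for Tjp1, 10.1 for Cldn4 and 9.31 for Cdh1 (E-cadherin). Foregut and gastric epithelium regulators had a peak at 15 of 20 promoters, which did not pass the test (adjusted exact p = 0.199), although 19 of 20 had one in replicate 2 alone (adjusted exact p = 0.00431) and in the pooled list (0.00562). Against CpG-matched genes, with 76.5%, the direction turned (adjusted permutation p = 1). Sox2, a factor of foregut progenitors, had an enrichment value of 14.9 (10.3 and 12.1 in the replicates), Gata4, a factor of the glandular stomach, 11.9 (7.70 and 11.9), Foxa3 18.4, Klf4 14.6 and Klf5 13.3. Hnf4a had a peak in the replicated list (4.20) and in replicate 2 (6.62) and none in replicate 1. Ehf had none in any list.

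Of 20 mature gastric gland products 1 had a promoter peak (adjusted exact p = 1.33e-05, lower than other genes): Bhlha15, a factor of secretory cells, with an enrichment value of 3.99. Atp4a and Atp4b, the subunits of the acid pump of parietal cells, had no peak in any list, nor did Aqp4. These promoters are poor in CpG, and matched genes had a peak in 12.9% of cases, and the call was lost against them (adjusted permutation p = 0.634). At that share even 0 of 20 would have given an unadjusted permutation p of 0.118, so the matched test could not have kept the call. Forestomach squamous epithelium genes had a peak at 2 of 20 promoters (adjusted exact p = 4.60e-05, and 0.0455 against CpG-matched genes), Perp (6.10) and Dsc3 (3.46). In replicate 2 alone 7 of the 20 had one (adjusted exact p = 0.0161) and in the pooled list 6 (0.00830), still called lower. Trp63, the regulator of stratified epithelia, had weak peaks in replicate 1 (3.67) and replicate 2 (3.45) and none in the replicated list. Enteroendocrine genes had a peak at 5 of 20 promoters (adjusted exact p = 0.00699), fewer than the 68.0% of CpG-matched genes (adjusted permutation p = 6.89e-04). The hormone cell genes Chga and Chgb and the factor Arx had none, while Isl1 (16.5), Mnx1 (7.98) and Insm1 (5.59) had one. Isl1 is also expressed outside endocrine cells.

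Among other cells of the stomach wall, 3 lists gave no call against all other genes and 2 lists of blood cells were called lower. Interstitial cells of Cajal and mesothelium had a peak at 9 of 14 promoters (adjusted exact p = 0.815), among them Tcf21 (26.6), Bnc2 (14.5) and Kit (12.5), the receptor of the pacemaker cells. The enteric nervous system had 10 of 20 (adjusted exact p = 0.554), with Hand2 at 19.7, Tbx3 at 10.6 and Gfra1 at 9.08, and lay below the 76.9% of CpG-matched genes (adjusted permutation p = 0.00496). In replicate 2 alone 15 of these 20 had a peak, and in the pooled list 16. Tbx3 also stands in the gastric mesenchyme and pluripotency lists, so its peak cannot be assigned to nerve cells. Endothelium had 11 of 20 (adjusted exact p = 0.823), with Ets1 at 11.3 and Fli1 at 8.10. Erythroid genes had 4 of 19 (adjusted exact p = 0.00292, and 1 against CpG-matched genes), with Klf1 at 11.4 and Tfrc at 11.3, and Alas2, Epb42 and Gata1 had no peak in any list. Leukocyte genes had 2 of 20 (adjusted exact p = 4.60e-05, and 0.226 against CpG-matched genes), Runx1 (8.59) and Ikzf1 (6.12). In replicate 2 alone 12 of these 20 had a peak, and the call was lost (adjusted exact p = 0.872).

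Genes of other organs were marked less often. The shares were 2 of 20 for liver (adjusted exact p = 4.60e-05), 4 of 20 for intestine (0.00169), 4 of 20 for pancreas (0.00169), 5 of 20 for heart (0.00699), 2 of 20 for skeletal muscle (4.60e-05), 5 of 20 for forebrain (0.00699), 2 of 20 for kidney and gonad (4.60e-05), 3 of 20 for germ cells (3.44e-04) and 3 of 15 for pluripotency (0.00538), each by Fisher's exact test. Lung and thyroid genes, with 7 of 20, did not pass (adjusted exact p = 0.0560) but were called lower in 5 of 10 other settings, with adjusted p from 0.0282 to 0.0473, among them replicate 1 alone and the pooled list. Spleen mesenchyme, with 4 of 8, gave no call (adjusted exact p = 0.777). Against CpG-matched genes the call held for heart (adjusted permutation p = 0.0191) and for skeletal muscle, forebrain, kidney and gonad, germ cells and pluripotency (6.89e-04 each), and was lost for liver (0.106), intestine (0.0589) and pancreas (0.0971). Alb, the liver's albumin gene, had no peak in any list, Cdx2, the intestinal master regulator, had one in replicate 2 (3.46) and the pooled list (2.93), and Pdx1, a factor of pancreas and distal stomach, had one in every list (5.32 in the replicated list). The liver exceptions were Apoh (9.47) and Hnf1a (7.45). The calls for pancreas, heart, forebrain and pluripotency were lost in replicate 2 alone, with adjusted p between 0.0555 and 0.290, and that for heart also in the pooled list (0.119) and with a 2500 bp window (0.0519). Kidney and gonad genes had 5 of 20 in replicate 2 alone (adjusted exact p = 0.00146) and 8 of 20 in the pooled list (0.0473), still called lower.

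Growth and signalling genes were marked more often than all other genes. All 20 cell cycle and replication genes had a promoter peak (adjusted exact p = 1.04e-04), with enrichment values of 18.9 for Mki67 and 17.8 for Cdk1, as did all 20 housekeeping genes (adjusted exact p = 1.04e-04), with 34.3 for Actb and 31.1 for Eef1a1. Genes of the Hedgehog, Wnt, BMP, FGF and retinoid pathways had a peak at 27 of 30 promoters (adjusted exact p = 7.46e-04), led by the Hedgehog receptor components Ptch1 (29.4) and Smo (26.3). Dkk1, an inhibitor of Wnt signalling, had none in any list. Histone deacetylases and acetyltransferases, the enzymes that remove and set such marks, had 18 of 19 (adjusted exact p = 0.00152), with Ep300 at 30.9 and Crebbp at 23.1. Against CpG-matched genes the housekeeping (adjusted permutation p = 0.0257) and histone enzyme lists (0.00733) stayed higher, while the cell cycle (0.307) and signalling lists (0.0780) did not pass, the former although it was at 20 of 20. With 1 start per gene the histone enzymes had 15 of 19 and no longer passed (adjusted exact p = 0.0540). The matched test was not run with 1 start per gene.

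**Figure D2:**
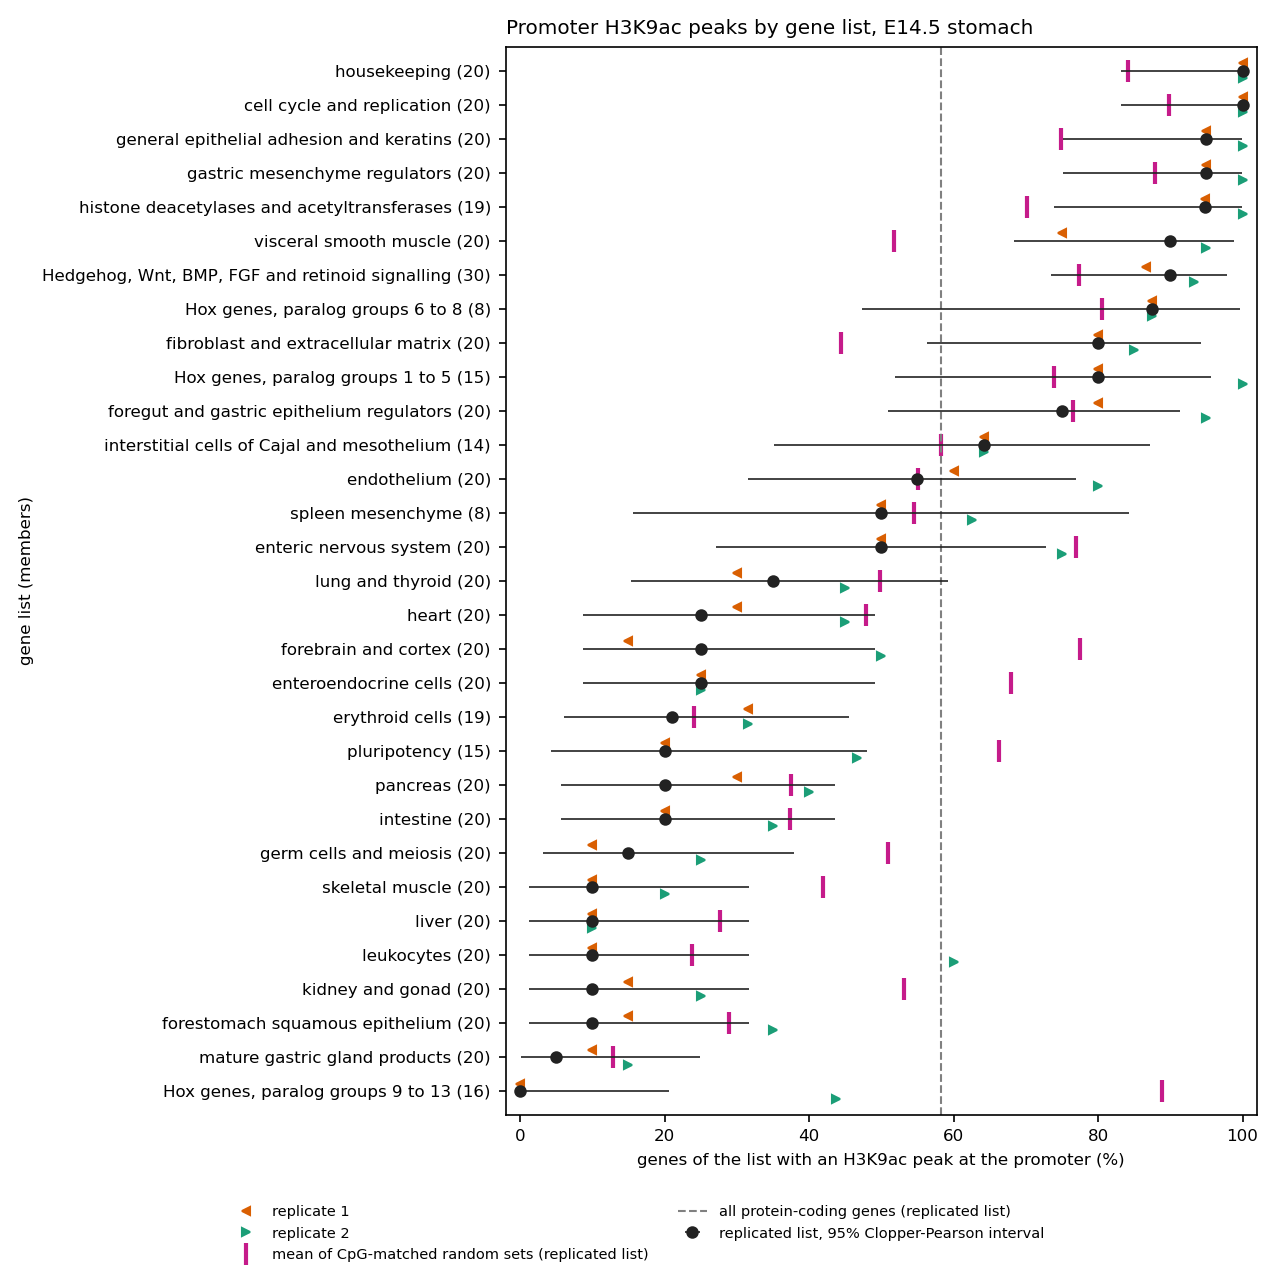
Share of each gene list's members with an H3K9ac peak within 1000 bp of a transcript start (x axis, %), for the 31 lists (y axis, members in brackets): black points are the replicated list with 95% Clopper-Pearson intervals, triangles the replicates, bars the mean of CpG-matched random sets, and the dashed line all protein-coding genes (58.2%). Smooth muscle (18 of 20) and fibroblast genes (16 of 20) lie above their matched sets, and Hox genes of groups 9 to 13 (0 of 16) lie below.

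As classes, lists chosen for the stomach had promoter H3K9ac more often than lists chosen for other organs. The stomach class also held the signalling list, the general epithelial and fibroblast lists and Hox groups 1 to 8. The other class also held the germ cell and pluripotency lists and Hox groups 9 to 13, so the classes differ in more than the organ. Single lists crossed: mature gastric products (5%), forestomach (10%) and enteroendocrine genes (25%) lay no higher than heart (25%), lung and thyroid (35%) or spleen mesenchyme (50%). Among genes of the stomach lists 150 of 235 (63.8%, interval 57.3 to 70.0%) had a promoter peak, against 35 of 209 (16.7%, interval 12 to 22.5%) in the lists of other organs (Fisher's exact test, odds ratio 8.77, p = 1.12e-24). The replicates alone gave 148 against 35 genes and 174 against 70 genes of the same totals. With labels moved only between genes of like CpG ratio the difference remained past the threshold (permutation p = 2.0e-04, the smallest the random sets allow). Gastric regulators of mesenchyme and epithelium had a promoter peak at 34 of 40 genes (85.0%, interval 70.2 to 94.3%), against 1 of 20 mature gastric products (5%, interval 0.127 to 24.9%), with an odds ratio of 108 (Fisher's exact test, p = 1.49e-09). The 2 classes differ in promoter CpG ratio, with medians of 0.715 and 0.167, and within genes of like ratio the call was lost (permutation p = 0.294). Only 2 CpG deciles held genes of both classes, with 6 regulators and 8 products, so the matched test rested on few genes.

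Hox genes, which set position along the body axis, were marked by paralog group. Promoter peaks were present at 12 of 15 genes of groups 1 to 5 (Fisher's exact test, adjusted exact p = 0.144), at 7 of 8 of groups 6 to 8 (adjusted exact p = 0.180) and at 0 of 16 of groups 9 to 13 (adjusted exact p = 1.33e-05). The last group lay far below the 88.8% of CpG-matched genes (adjusted permutation p = 6.89e-04). In replicate 2 alone, 7 of the 16 had a peak, with enrichment values up to 4.94, and the call was lost (adjusted exact p = 0.157). In the pooled list 4 of 16 had one (adjusted exact p = 0.00669). As these genes lie in clusters they are not independent, and with 1 gene per 100 kb the count was 0 of 4 (adjusted exact p = 0.0429). Groups 1 to 5 passed in replicate 2 alone with 15 of 15 genes (adjusted exact p = 0.00431). In the HoxA cluster on chromosome 6 the replicated peaks ran from 52158368, at the start of Hoxa1, to 52221769, at the start of Hoxa7, and none lay over Hoxa9 to Hoxa13. In the HoxB cluster on chromosome 11 they ran from 96282023, at the start of Hoxb8, to 96355338, past Hoxb2, and none lay over Hoxb9 or Hoxb13, nor over Hoxb1 at the other end of the cluster. These edges are those of the replicated list. Replicate 1 had peaks beyond them over Hoxa9 (2.78) and Hoxa10 (2.88). Replicate 2 had peaks beyond them too, among others over Hoxa9 (4.94), Hoxb9 (4.94) and Hoxb1 (4.44).

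**Figure D3:**
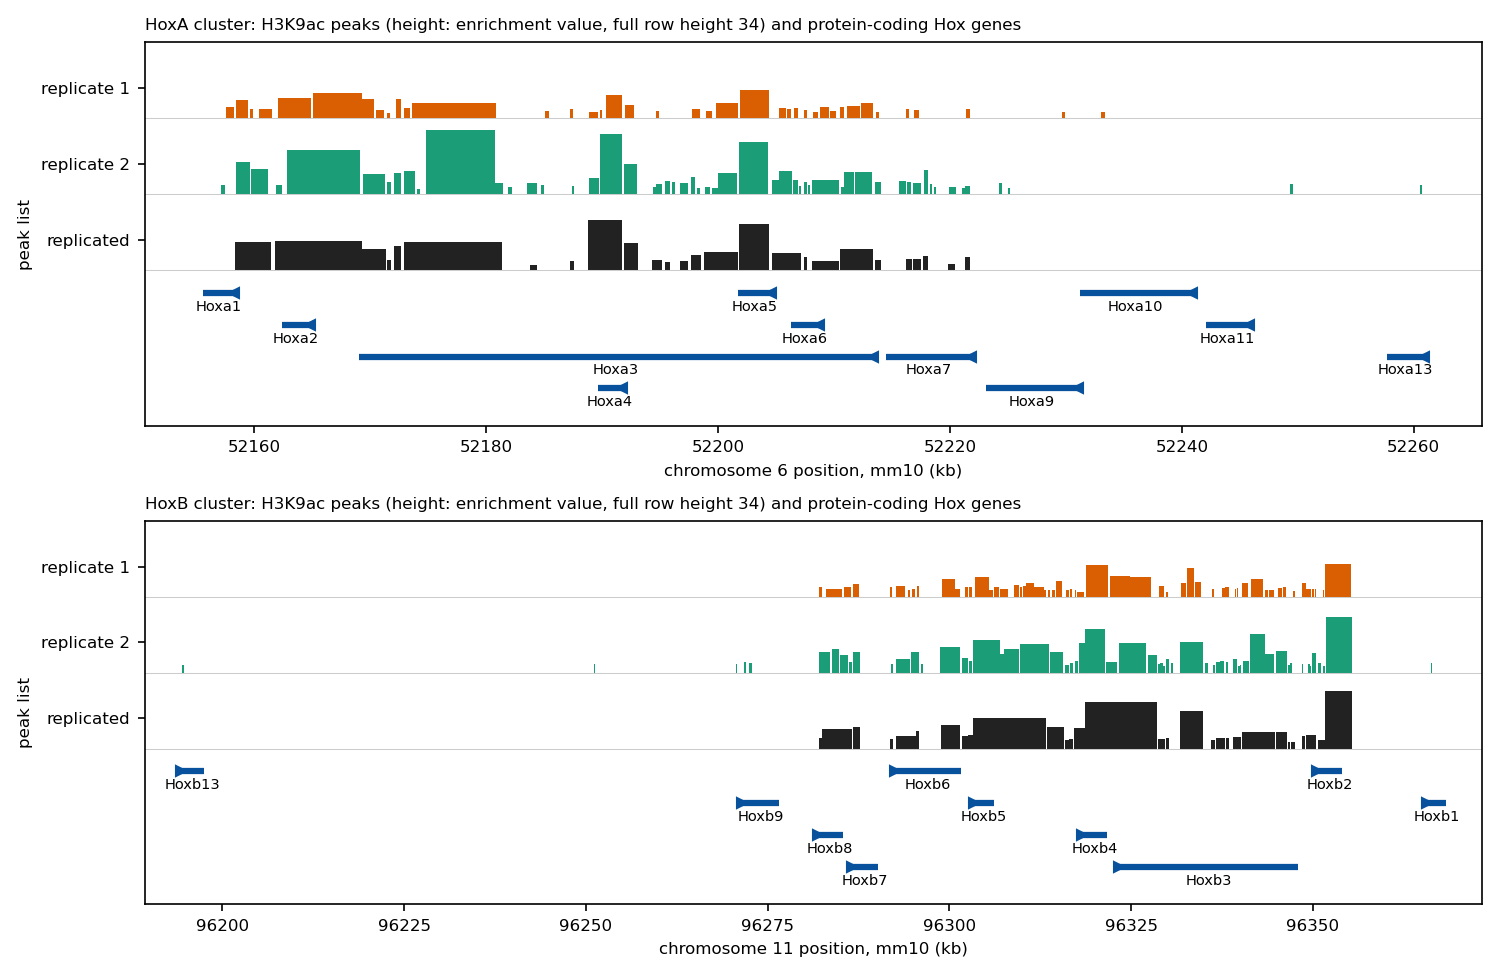
H3K9ac peaks of replicate 1, replicate 2 and the replicated list (rows, bar height the enrichment value, which is not scaled between lists) over the HoxA and HoxB clusters (x axis, mm10 position in kb), with protein-coding Hox genes in blue and an arrowhead at each gene's start. The replicated peaks end at Hoxa7 (52221769) in HoxA and begin at Hoxb8 (96282023) in HoxB.

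After peaks up to 1000 bp apart were joined, the widest H3K9ac region spanned 31336 bp at chromosome 11, 96298895 to 96330230, over the starts of Hoxb3, Hoxb4, Hoxb5 and Hoxb6. It was followed by 25173 bp at Nr2f2 (chromosome 7, 70345440 to 70370612), 23061 bp at Hoxa2 and 5730596B20Rik (chromosome 6, 52158368 to 52181428), 19660 bp over Hoxa3, Gm28308, Hoxa5 and Hoxa6, 19362 bp over Hoxb2 and Hoxb3, and 17288 bp at Meis2. Regions of 14779 bp at Meis1, 14042 bp at Pitx1, 13963 bp at Ptch1, 12979 bp at Foxf1, 12627 bp at Tbx2, 12023 bp at Hand2, 11950 bp at Foxa1 and 11681 bp at Barx1 came next but for 1. That region, at chromosome 18, 61651025 to 61666392 (15368 bp), covered no protein-coding start. It lay over the long intergenic RNA gene Carmn (61649625 to 61665537, minus strand), and the nearest protein-coding start, that of Il17b, was 21543 bp from the region. The remaining 5 of the 20 widest lay at Tnrc18, Isl1, Igf2, Zfp503 and Setd1b.

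The 20 widest regions covered the starts of 26 protein-coding genes, of which 22 were also among the genes of the 20 widest regions of replicate 1 and 22 among those of replicate 2. The region at Tbx2 measured 3217 bp in replicate 1 and 14830 bp in replicate 2. With peaks joined only where they touch, 11 of the 26 genes remained.

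The highest replicated peak lay at chromosome 7, 73555955 to 73558569, with an enrichment value of 46.6 (30.9 and 50.9 in the replicates). It covered the start of the non-coding gene 1810026B05Rik and was 14209 bp from the nearest protein-coding start, that of the chromatin remodeller gene Chd2. The other peaks of the top 10 covered starts of Bicral (39.4), Adnp (39.1), Sfpq (37.2), Tnrc18 (36.7), Irf2bp2 (36.7), Srsf6 (36.2), Ptma (35.9), Rps19 (35.4) and Hnrnpu (35.0).

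Away from transcript starts H3K9ac was weaker and less often found in both replicates. Of 20337 replicated peaks 2374 (11.7%, interval 11.2 to 12.1%) lay more than 2500 bp from every annotated start, with a median enrichment value of 4.25 against 7.98 for the others. The strongest was an intergenic peak at chromosome 7, 73618600 to 73619437 (23.2), 76854 bp from Chd2, with another at 73616541 to 73618415 (19.1). Others lay in an intron of Prdm2 (chromosome 4, 143160776 to 143162204, 19.7), 37821 bp from Ptma (18.9), in an intron of Hoxb3 (chromosome 11, 96331709 to 96334938, 16.8) and 23958 bp from Smad7 (16.8). Distal peaks made up 31.4% of the list of replicate 1 and 44.1% of that of replicate 2, and only 13.5% and 4.92% of them were overlapped in the other replicate, against 77.6% and 47.0% of the peaks nearer to a start.

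The X chromosome carried few peaks for its length. It had 3.12 replicated peaks per Mb, below the autosomes, which ranged from 5.06 on chromosome 14 to 14.6 on chromosome 11 with a median of 8.30. Of its protein-coding genes 39.2% had a promoter peak, against 46.7 to 70.8% across autosomes. The ratio of the X chromosome to the autosomal median was 0.376, and 0.285 and 0.237 in replicate 1 and replicate 2.

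The replicates gave the same regions where the signal was strong. Of the peaks of replicate 1, 57.5% (20729 of 36081) were overlapped by a peak of replicate 2 over at least 50% of the shorter peak, against 1.74% for peaks placed at random. Of the longer list of replicate 2, 28.5% (18481 of 64919) were overlapped, against 0.966% at random. With the list of replicate 2 shortened to the length of the other, 47.7% of it was overlapped, and overlap of at least 50% of both peaks gave 37.2% of replicate 1 and 20.7% of replicate 2. In the decile with the lowest p, 100% of replicate 1 and 99.9% of replicate 2 peaks were shared, and in the decile with the highest p 19.8% and 3.36%. The share of replicate 1 did not fall steadily, with 19.0% in decile 7, 32.1% in decile 8 and 10.6% in decile 9. Peaks with the same p were ordered by position. Across the 20729 shared peaks, which are not independent replicates, Spearman's rho of the enrichment values was 0.600 and Pearson's r of their log2 values 0.61. Shared peaks of replicate 1 had a median enrichment value of 5.09 against 2.99 for the others.

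**Figure D4:**
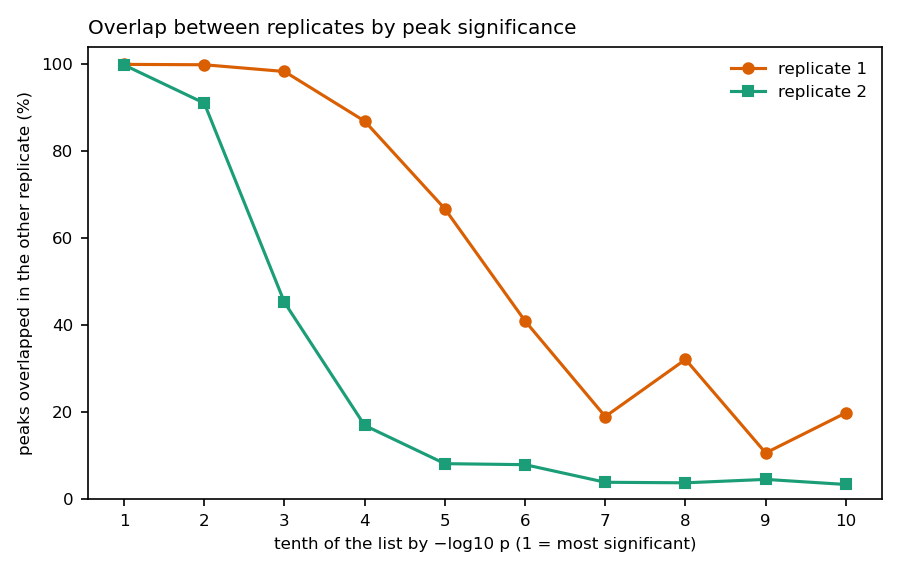
Share of peaks overlapped in the other replicate over at least 50% of the shorter peak (y axis, %), by decile of each replicate's list ordered by −log10 p (x axis, 1 the most significant). Replicate 1 stays at or above 98.4% through its first 3 deciles, and replicate 2 falls to 45.2% in decile 3.

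Genes of the lists that had a promoter peak in 1 replicate were mostly those of replicate 2. Of 566 list genes 82 had a promoter peak in replicate 2 and not in replicate 1, the highest being the muscle intermediate filament gene Des (11.5), the lymphoid factor Ikzf1 (8.39), Hhex (7.90) and Hnf4a (6.62). In replicate 1 and not in replicate 2 there were 6, Myl7 (3.64), Aif1, Cel, Ghrl and Nphs1 (3.31 each) and Cdh5 (2.94).

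All 20341 replicated peaks were identical to peaks of the pooled list. Of these, 17841 (87.7%) overlapped a peak of replicate 1 by at least 1 bp and 20041 (98.5%) a peak of replicate 2. The 17544 pooled peaks overlapped in both replicates over at least 50% of either peak were all in the replicated list and made up 86.2% of it. A further 2500 replicated peaks (12.3%) overlapped no peak of replicate 1, with a median enrichment value of 4.00 against 8.27 for those overlapped in both, 300 overlapped none of replicate 2, and 42 overlapped neither.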

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

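The sensitivity and blood tests of the leukocyte genes and the gene family test of the X chromosome were chosen only after the result was seen. The CpG-matched sets were chosen before, but were read as tests of a cause of the low gastric lists only after.

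The comparisons of genes above used neither peaks on scaffolds nor long non-coding RNA genes. The replicated list held 4 peaks on unplaced or unlocalized scaffolds, with enrichment values of up to 10.6. A replicated peak also lay within 1000 bp of a start of 479 long non-coding RNA genes whose starts are more than 2000 bp from every protein-coding start, 5.81% of 8241 such genes (interval 5.32 to 6.34%). The distance was set for starts and not for peaks, so some of these peaks were already used above. The peak at Gm16140 and Gm16141 is the one that covers the start of Meis1. How many of the 479 genes share a peak with a protein-coding start was not counted.

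Leukocyte genes had a promoter peak at 2 of 20 genes in replicate 1 and at 12 of 20 in replicate 2. Of the 18 without a replicate 1 peak, 11 (61.1%) had one in replicate 2, among them Spi1, Csf1r, Adgre1 and Coro1a (chosen after their values were seen, enrichment values 3.46 to 4.94). CpG-matched genes without a replicate 1 peak gained one in 16.6% of cases (adjusted permutation p = 0.00580 over 29 lists, the only list to pass). A higher sensitivity of replicate 2 stays open, since these genes were not matched on weak signal below the threshold of replicate 1. The gained leukocyte peaks had a median enrichment value of 3.79 in replicate 2, against 3.95 for all gained genes. Of the 11, 6 had a −log10 q of at least 2. Blood carried along stays open: 0 of 13 erythroid genes gained a peak (Fisher's exact p = 4.38e-04 against the leukocyte list), but CpG-matched genes gained one in only 7.25% of cases, so 0 lay within expectation (permutation p = 0.740). More leukocytes in the tissue of replicate 2 may be a source, but a second list of 30 leukocyte genes without shared members gained 8 of 25 (32.0% against 15.9% expected, permutation p = 0.0514), which leaves it open, and Ptprc and Lyz2 had no peak in either replicate.

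X-linked genes had fewer promoter peaks than autosomal ones. Promoter CpG content does not account for all of it, since matched autosomal genes had a peak in 48.0% of cases against 39.2% (permutation p = 2.0e-04, the smallest the random sets allow). Families of 5 or more like-named genes on a chromosome, left out everywhere together with genes without a name, raised the X-linked share to 57.3% of 550 genes against 64.0% of matched autosomal genes (permutation p = 2.0e-04 again), although in the comparison run first, against all autosomal genes with families included, the difference was not past the threshold (59.5%, permutation p = 0.144). A single active X chromosome is a candidate explanation that the data leave open: X-linked promoter peaks had a median enrichment value of 6.92 against 9.77 in matched autosomal sets (range of 95% of sets 9.13 to 10.4, permutation p = 2.0e-04). With families included, chromosome 14, the autosome with the lowest share, also lay below its matched share (46.7% against 51.7%, permutation p = 2.0e-04). Chromosome 7 lay above its own (47.6% against 45.4%, permutation p = 1.0e-03). A low share with families included was thus not particular to the X chromosome. Chromosome 14 was not tested without families or for the enrichment value.

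Mature gastric products and enteroendocrine genes both had few promoter peaks. Whether promoter CpG content accounts for the gastric products stays open: they had 5% against 12.9% in matched genes (adjusted permutation p = 0.634, where it was 1.33e-05 against 58.3% of all other genes). The call ended because the expected share fell, and at that share even 0 of 20 would have given an unadjusted permutation p of 0.118. For the enteroendocrine genes CpG content is not enough, with 25% against 68.0% (adjusted permutation p = 6.89e-04). No biological explanation was tested, since no other stage or organ was sampled.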

How the results depend on the processing

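The pooled peaks overlapped in both replicates and the reciprocal overlap of the replicated list were chosen only after the data were seen. Of 22 called lists, 7 kept their direction and call in all 10 alternatives: enteroendocrine cells, forestomach squamous epithelium, general epithelial adhesion and keratins, germ cells and meiosis, housekeeping, kidney and gonad, and skeletal muscle. CpG matching ended 9 of the 22 calls, by raising or lowering the expected share, and added 2. For gastric mesenchyme regulators, mature gastric products and cell cycle genes no count could have passed that test in the direction called (lowest unadjusted permutation p in that direction = 0.0914, 0.118 and 0.218). The lists called lower numbered between 9 (replicate 2 alone) and 16 (replicate 1 alone), and those called higher between 5 and 9. With CpG-matched sets the difference between gastric regulators and mature products, 80.0 percentage points, lost its call (permutation p = 0.294). Matching changes only the expected share, so the observed difference could not move. In the other 8 alternatives p was at most 5.42e-09 (Fisher's exact test). The stomach lists exceeded the other-organ lists by 40.5 to 47.4 points, past the threshold in all 9 alternatives. Lists not called changed direction as follows: endothelium, 80.0% in the pooled list and 60.0 to 80.0% in the replicates; enteric nervous system, 80.0% in the pooled list and 75.0% in replicate 2 alone (50% in replicate 1); foregut epithelium, 75.0% with CpG-matched sets; interstitial cells and mesothelium, 50% with 1 start per gene.

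The lists that were not filtered for replication held more weak peaks outside promoters. The promoter share was 40.1% in the pooled list and 34.6 to 50.8% in the replicates, exons 8.48% and 6.49 to 8.19%, introns 33.7% and 26.7 to 36.2%, intergenic sequence 17.7% and 16.0 to 21%, and distal peaks 37.6% and 31.4 to 44.1%. A 500 bp window gave 54.8% promoter, 10.9% exon and 23.7% intron, and a 2500 bp window 3.71% exon, by its construction. The ratio of the X chromosome to the autosomal median was 0.251 in the pooled list and 0.237 to 0.285 in the replicates. Sharing of replicate 1 peaks rose to 80.8% at the stricter threshold. Spearman's rho was 0.773 with reciprocal overlap, 0.759 with peaks joined first and 0.585 at the stricter threshold. Reciprocal overlap left 58.3% of the replicated list overlapped in both replicates. The median width of the 20 widest regions, 13.5 kb, was 7.001 kb when only touching peaks were joined and 16.1 kb in the pooled list. Where no construction is named, the cause was not tested. No paired analysis was possible because there was only 1 group. Read depth is unknown, so how far it limits the shorter list of replicate 1 cannot be given.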

Other observations

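The tests of wide regions and of gene families were chosen only after the data were seen.

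Gene families differed in promoter H3K9ac, also from genes of like CpG ratio. Of 1135 olfactory receptor genes 1 had a replicated promoter peak (7 in replicate 1, 10 in replicate 2), against 7.37% of CpG-matched genes, and of 329 vomeronasal receptors 1, against 6.17% (adjusted permutation p = 7.0e-04 each). Of 64 defensin genes none had a peak in the replicated list or in either replicate, against 10.4% (adjusted permutation p = 0.00327). Clustered protocadherins had 4 of 57, far below the 68.0% of matched genes (adjusted permutation p = 7.0e-04), and keratins 6 of 53 (12 in replicate 2), against 30.5% (adjusted permutation p = 0.00280). The marked keratins were Krt7, Krt8, Krt10, Krt18, Krt19 and Krt222, chosen after their values were seen. Above their matched genes lay the Zfp zinc finger genes (321 of 394, against 67.0%, adjusted permutation p = 7.0e-04), cytosolic ribosomal proteins (76 of 79, against 87.2%, 0.00560), proteasome subunits (38 of 40, against 80.5%, 0.00420) and collagens (31 of 45, against 55.3%, 0.0346). Histones of cluster 1 (44 of 54, against 91.6%, 0.0162) and potassium channels (48 of 94, against 63.6%, 0.00420) lay below. Cytochromes P450, interleukins and solute carriers did not pass (adjusted permutation p = 0.551, 0.256 and 0.0653). Families such as the clustered protocadherins and the histones of cluster 1 lie in gene clusters, so their genes are not independent. The matched sets took no account of this, and no test with 1 gene per 100 kb was run for families. Loss of peaks at near-identical copies was not tested either.

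Among long non-coding RNA genes with strong peaks at their starts, named after their values were seen, was Mir17hg, host of a microRNA cluster (chromosome 14, peak at 115040275 to 115042954, enrichment value 26.6). Gm20342 (31.9) and Tug1 (24.7) had no overlapping peak at these starts in replicate 1. This speaks only to the starts, and overlap of their replicated peaks with replicate 1 peaks was not tested.

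Wide regions may lie at regulators of the gastric mesenchyme more often than at other genes with a peak, a hypothesis that came from the widest regions themselves. Of 12771 genes with a promoter peak 174 (1.36%) had a start in a joined region of 5 kb or more. Among gastric mesenchyme regulators 11 of 19 did: Barx1, Foxf1, Foxf2, Isl1, Meis1, Meis2, Nr2f1, Nr2f2, Pbx1, Six2 and Tbx2. The 26 genes of the 20 widest regions had been seen when this was chosen. Without them 4 of 12 remained (33.3%, against 1.4% in CpG-matched genes with a peak, adjusted permutation p = 0.00300 over 30 lists), Foxf2, Nr2f1, Pbx1 and Six2. The excess was not particular to this list. Without the same 26 genes, foregut and gastric epithelium regulators had 3 of 14, spleen mesenchyme 2 of 4 and the signalling list 6 of 26 (adjusted permutation p = 0.00300 each), and Hox groups 6 to 8 had 2 of 5 (0.0156). The spleen genes were Tcf21 and Pbx1, and Pbx1 is also counted among the gastric mesenchyme regulators. The Hox genes were the neighbours Hoxb7 and Hoxb8, whose starts lie in the same joined region, so they are not separate observations. Hox groups 1 to 5 then had 0 of 5, and enteroendocrine genes (1 of 4, 0.470) and the enteric nervous system (1 of 9, 0.604) did not pass, although with all genes they had (2 of 5, 0.0309, and 2 of 10, 0.0412).

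Distal peaks lay next to genes of the stomach lists more often than to those of other organs, as had been put forward before the count. Of 235 stomach list genes 67 (28.5%, interval 22.8 to 34.7%) were the nearest gene of a distal replicated peak, against 23 of 209 (11%, interval 7.11 to 16.1%) and 7.68% of all protein-coding genes, by Fisher's exact test between the list classes p = 5.39e-06 and within genes of like CpG ratio permutation p = 8.0e-04. Among genes that had a promoter peak themselves the counts were 61 of 150 and 5 of 35 (Fisher's exact test, p = 0.00310). Foxa1, Meis1, Nr2f1, Col1a1 and Mylk, chosen after their values were seen, had 6 such peaks each. Genes in none of the lists had more, led by Bcor and Gse1 with 10 each. Neither test matched genes on the distance to their neighbours, which affects how often a gene is the nearest. Which gene a distal peak acts on was not tested, and the nearest gene may be another (Fisher's exact p = 5.39e-06 speaks only to position).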
